A study of Rattus norvegicus with 4 samples.

How the data were processed

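RNA was sequenced from neonatal rat ventricular myocytes, the contracting muscle cells of the newborn heart ventricle kept in primary culture. Per the labels' protocols, cells from 2-day-old Sprague Dawley hearts were transfected for 6 h with an siRNA against the long noncoding RNA Chaer or with a negative control siRNA, and RNA was collected after 48 h with or without 50 µM phenylephrine. Stranded TruSeq libraries were made from total RNA, per the labels' protocols. There were 4 libraries, 1 for each combination of siRNA and treatment, so no group had a replicate, and nothing in the labels says that the libraries came from separate cultures.

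The submitters' processing notes name TopHat2 for the alignment and the genome build rn5. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. Per the file headers, the authors deposited a whole-number read count and an RPKM value (reads per kilobase of gene model, scaled to a common sequencing depth) for each feature. The same 26406 features were listed in each library. Dividing counts by RPKM gave, for every feature with over 1000 reads, a whole gene length times a single read total per library, with lengths within 6.32e-08 bp of a whole number. The read totals recovered in this way were 36989888 for control siRNA, 40394068 for Chaer siRNA, 35314303 for control siRNA with phenylephrine and 40835172 for Chaer siRNA with phenylephrine. Between 3.88% and 4.29% of those reads were not in the listed features.

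Of the 26406 features, 26405 carried only an Ensembl gene identifier and 1, H19, carried a symbol. The reference table used here (assembly GRCr8) pairs 0 of these identifiers with a symbol, so genes are given by identifier, at most 2 higher and 2 lower in each of the 2 main comparisons. The 26 gene lists of pathways and cell types fixed before the data were examined could therefore not be applied. No feature was named Chaer, so the knockdown of the target was not checked here. No coordinates are printed, because the reference assembly differs from the build of the files.

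Ratios were computed as planned, as the log2 of (RPKM + 1) in one library over (RPKM + 1) in the other. This understates the change of weakly expressed genes, and the ranks of features follow this measure. The 12226 features with a mean RPKM of at least 1 over the 4 libraries were compared, and a ratio of at least 2-fold was counted as passing the size rule. With 1 library per group this rule carries no p-value and no check against replicates. The difference of the phenylephrine effects was the log2 ratio with Chaer siRNA minus that with control siRNA. Correlations of these ratios were taken between comparisons that share no library, across genes, which are not independent replicates. The contrasts of the additive fit described below use the same 4 libraries, and their correlation was set beside 20 simulations with no effect of either factor. The overlap of their calls was set beside that of independent lists, over all genes and within 10 bins of mean reads. Intervals at 95% were exact binomial for a ratio of 2 libraries, exact Poisson for an RPKM value, and a normal approximation on log counts (with 0.5 reads added) for the difference of the effects. They cover counting error only, and reads without molecular identifiers are not independent molecules. Where a library had 0 reads, the limit was taken as 3 reads, which for a gene of 1 kb is 0.0735 to 0.0850 RPKM.

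The plan foresaw RPKM values alone. Because read counts were also present, an edgeR quasi-likelihood fit of siRNA plus phenylephrine over the 4 libraries was added after seeing the files (TMM scaling, Benjamini-Hochberg adjusted p under 0.05). It sets 2 libraries against 2 for each factor and leaves 1 residual degree of freedom, namely the departure from additivity. The estimated prior degrees of freedom were infinite, so the spread came from a trend over all genes and not from each gene's own deviation. The common biological coefficient of variation was 0.111. The p-values therefore assume that both effects add and that these libraries vary as replicates would, which was not measured.

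On simulated counts with this spread and 12226 genes, the fit called 47 of 50 genes raised 2-fold, 45 of 50 lowered 2-fold and 50 of 50 changed 4-fold in each direction for phenylephrine, with 4 calls among 12026 unchanged genes. For Chaer siRNA it called 48 of 50, 47 of 50 and again 50 of 50 in each direction, with 10 calls among 12026 unchanged genes. The size rule was tested on Poisson counts of the phenylephrine comparison with control siRNA. It passed 16 of 50 genes raised exactly 2-fold, 6 of 50 lowered 2-fold, 50 of 50 raised 4-fold and 45 of 50 lowered 4-fold, with 4 of 12026 unchanged genes passing.

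Named features were H19 and the 2 largest and 2 smallest ratios for phenylephrine with control siRNA and for Chaer siRNA with phenylephrine. The rule fixed before the data were examined took more genes per direction. It covered every comparison and the difference of the phenylephrine effects, and left out uncharacterised genes, which needs symbols. The cut to 2 per direction in 2 comparisons was not part of that rule. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean RPKM of at least 5), 3 other scalings, the size rule (1.5-fold and 4-fold) and a counting interval that excludes 1. A correlation or slope was taken as unmoved within 10% of its main value. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.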

Results

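The transcriptome of neonatal rat ventricular myocytes was measured in 4 libraries that combined 2 siRNAs with and without phenylephrine, an agonist of α1-adrenergic receptors that makes these cells grow in a model of cardiac hypertrophy. Chaer is a long noncoding RNA associated with cardiac hypertrophy, and the series asked what it contributes to the transcriptional response to phenylephrine. The libraries held 35404497 reads in listed genes for control siRNA, 38768299 for Chaer siRNA, 33944988 for control siRNA with phenylephrine and 39155363 for Chaer siRNA with phenylephrine. A few abundant features took a large part of these reads. The 20 features with the most reads held 24.7% in the control siRNA library and 20.5%, 21.5% and 20.4% in the libraries with Chaer siRNA, control siRNA plus phenylephrine and Chaer siRNA plus phenylephrine. Each group was a single library, so no value below has an error estimated from replicate cultures. The intervals of levels, ratios and differences are 95% counting intervals. Those of shares of features are exact binomial over genes, and SEs come from the additive fit.

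H19, an imprinted long noncoding RNA that is abundant in the fetal heart and the only feature listed under a symbol, was lower with Chaer siRNA in both conditions. Without phenylephrine its level was 30.6 RPKM (29.5 to 31.8) with control siRNA and 5.52 RPKM (5.05 to 6.01) with Chaer siRNA, a ratio of 5.56 (5.05 to 6.12). With phenylephrine the corresponding levels were 20.1 RPKM (19.1 to 21.1) and 4.60 RPKM (4.18 to 5.06), a ratio of 4.37 (3.93 to 4.87). On the log2 scale with a pseudocount these ratios were -2.28 and -1.91, the 5th and the 4th lowest of the 12226 features with a mean of at least 1 RPKM. With a pseudocount of 0.1 in place of 1 they were the 13th and the 12th lowest. H19 differed less with phenylephrine. It was 1.52 times lower (1.43 to 1.62) with control siRNA and 1.20 times lower (1.05 to 1.36) with Chaer siRNA, neither of which reached 2-fold. In the additive edgeR quasi-likelihood fit, H19 fell by 2.31 ± 0.16 (SE) on the log2 scale with Chaer siRNA (adjusted p = 3.25e-43). Its phenylephrine term in that fit was -0.35 ± 0.15 (adjusted p = 0.114). The spread behind both came from departures from additivity over all genes and not from replicate cultures. A difference between cultures is therefore not covered by these SEs and p-values. With phenylephrine left out of the edgeR model, so that its effect entered the error, the Chaer siRNA term of H19 was -2.33 with an adjusted p = 0.0550, the highest over the settings run. The phenylephrine term passed with scaling by library size alone (edgeR adjusted p = 0.0404). The gene model of H19 was 2325 bp long. Reads of features that overlap it on the other strand can be told apart only if the counting used strand, which the sources used here do not state.

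Phenylephrine with control siRNA addressed the response of myocytes with Chaer left in place. Of 12226 features, 137 were at least 2-fold higher and 74 at least 2-fold lower with phenylephrine, 1.73% in all. ENSRNOG00000008141 had the highest ratio of (RPKM + 1), from 163 RPKM (157 to 168) to 1636 RPKM (1620 to 1653), which is 10.1-fold (9.73 to 10.4). ENSRNOG00000014231 came next by that measure, with 0 reads without and 288 reads with phenylephrine. Its level was 100.5 times that of a floor of 3 reads in the untreated library, and with the counting error of both libraries it was at least 81.25-fold higher. It ranked first with a pseudocount of 0.1, where the log2 ratios were 6.35 for it and 3.33 for ENSRNOG00000008141, and on the TPM scale, where they were 3.87 and 3.37, but 34th with a pseudocount of 5, at a log2 ratio of 1.38. The lowest ratios of (RPKM + 1) were those of ENSRNOG00000023943, from 65.6 RPKM (63.7 to 67.6) to 12.4 RPKM (11.6 to 13.3), and ENSRNOG00000050450, from 24.6 RPKM (22.9 to 26.3) to 5.44 RPKM (4.65 to 6.33). Poisson draws with no change at these depths put a median of 3 and at most 8 features past 2-fold in 100 draws. Such draws, here and below, hold counting error only. They leave out variation between cultures, so they cannot tell an effect of treatment from a difference between cultures. Higher features made up 64.9% of those past 2-fold, and 54.0% when the 20 most abundant genes were left out of the scaling. With a pseudocount of 0.1, 182 were higher and 169 lower, and with the 1.5-fold rule 433 and 491.

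Phenylephrine with Chaer siRNA gave about as many features at least 2-fold higher as with control siRNA, and more at least 2-fold lower. Higher were 134 features, against 137 with control siRNA, and lower were 107, against 74. ENSRNOG00000008141 was 6.00-fold higher (5.87 to 6.12) here, from 401 RPKM to 2406 RPKM, so that its level with phenylephrine exceeded that of the control siRNA library while its ratio was smaller. ENSRNOG00000023943 was 3.44 times lower (2.89 to 4.10) and ENSRNOG00000050450 4.01 times lower (3.32 to 4.87). Poisson draws of counting error alone gave a median of 2 and at most 7 features. Of the features past 2-fold, 55.6% were higher, and 70.6% under median-ratio scaling. With a pseudocount of 0.1, however, 200 were higher and 224 lower, and with the 1.5-fold rule 522 and 723. The larger direction thus depended on the measure.

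**Figure D1:**
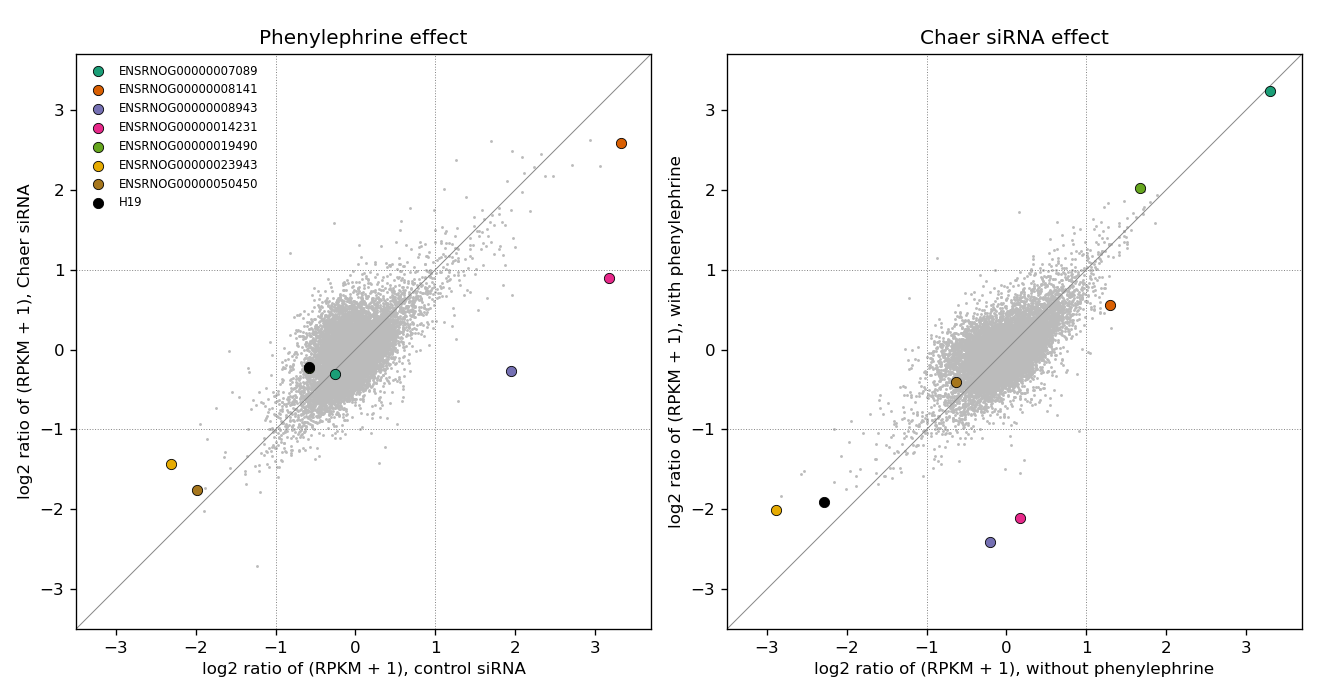
Log2 ratios of (RPKM + 1) for 12226 features (grey points), with the phenylephrine effect under control siRNA (x) and Chaer siRNA (y) on the left and the Chaer siRNA effect without (x) and with phenylephrine (y) on the right. Coloured points are H19 and 7 features given by identifier, dotted lines mark 2-fold and the diagonal marks equal ratios; most points far from the origin lie near the diagonal (r = 0.63 and 0.65), and ENSRNOG00000008943 and ENSRNOG00000014231 lie away from it.

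The same features tended to respond under both siRNAs, whose phenylephrine ratios come from separate libraries. Of the features at least 2-fold higher, 90 were shared between the 137 and the 134, against 1.5 for independent lists. Of those at least 2-fold lower, 37 were shared between the 74 and the 107, against 0.648. In both directions, 0 features were 2-fold higher under one siRNA and 2-fold lower under the other. Across genes, the ratios correlated with Pearson's r = 0.63 and Spearman's rho = 0.49, and the total least squares slope of the Chaer siRNA ratio on the control siRNA ratio was 1.15.

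The size of the response was compared on features chosen by their mean ratio over both siRNAs, which favours neither if both ratios spread equally. Across all features the SD was 0.35 with control and 0.38 with Chaer siRNA, so the choice leans towards larger Chaer siRNA ratios. Of 127 features with a mean of at least 2-fold higher, 79 (62.2%, exact binomial interval 53.2% to 70.7%) had the smaller ratio with Chaer siRNA, and the median log2 ratios were 1.36 with control and 1.29 with Chaer siRNA. Of 73 with a mean of at least 2-fold lower, 21 (28.8%, 18.8% to 40.6%) had the smaller ratio with Chaer siRNA, with median log2 ratios of -1.05 and -1.26. The median difference between the siRNAs was -0.11 for the raised and -0.17 for the lowered features, beside -0.06 for all 12226. After centring on that shift, the shares became 55.1% (46.0% to 63.9%) and 32.9% (22.3% to 44.9%). These intervals treat genes as independent, which they are not. For lowered features the share depended on the choice, at 63.5% when chosen on the control siRNA ratio alone and 9.35% on the Chaer siRNA ratio alone.

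Chaer siRNA without phenylephrine addressed how myocytes given this siRNA differed at baseline. At least 2-fold higher were 125 features and at least 2-fold lower 136, and Poisson draws of counting error alone gave at most 7. ENSRNOG00000007089 had the highest ratio, from 9.38 RPKM (8.67 to 10.1) to 101 RPKM (98.5 to 103), which is 10.7-fold (9.90 to 11.7). ENSRNOG00000023943 had the lowest ratio of (RPKM + 1), and an RPKM 8.16 times lower (7.48 to 8.91); it was the 4th lowest with a pseudocount of 0.1. ENSRNOG00000008141 was 2.47-fold higher (2.38 to 2.56) before any phenylephrine. Higher features were 47.9% of those past 2-fold, and 35.1% when the 20 most abundant genes were left out of the scaling.

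Chaer siRNA with phenylephrine addressed how myocytes given this siRNA differed under stimulation. At least 2-fold higher were 122 features and at least 2-fold lower 104, again against at most 7 in draws of counting error alone. With a pseudocount of 0.1 the counts were 187 and 246, so the larger direction turned. ENSRNOG00000007089 led again, from 7.69 RPKM (7.03 to 8.40) to 81.3 RPKM (79.3 to 83.4), which is 10.6-fold (9.64 to 11.6), and ENSRNOG00000019490 was 4.32-fold higher (4.09 to 4.56). The lowest ratio of (RPKM + 1) was that of ENSRNOG00000008943, from 55.8 RPKM (53.6 to 58.0) to 9.65 RPKM (8.83 to 10.5), which is 5.78 times lower (5.25 to 6.37). ENSRNOG00000014231, less abundant, followed by that measure, though its RPKM was 7.40 times lower (5.39 to 10.4), from 288 reads to 45 reads. With a pseudocount of 0.1 the order turned, with log2 ratios of -2.52 for ENSRNOG00000008943 and -2.78 for ENSRNOG00000014231. The Chaer siRNA ratios without and with phenylephrine also come from separate libraries and correlated across genes with r = 0.65 and rho = 0.54. They shared 78 features at least 2-fold higher, against 1.25 for independent lists, and 61 at least 2-fold lower, against 1.16.

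**Figure D2:**
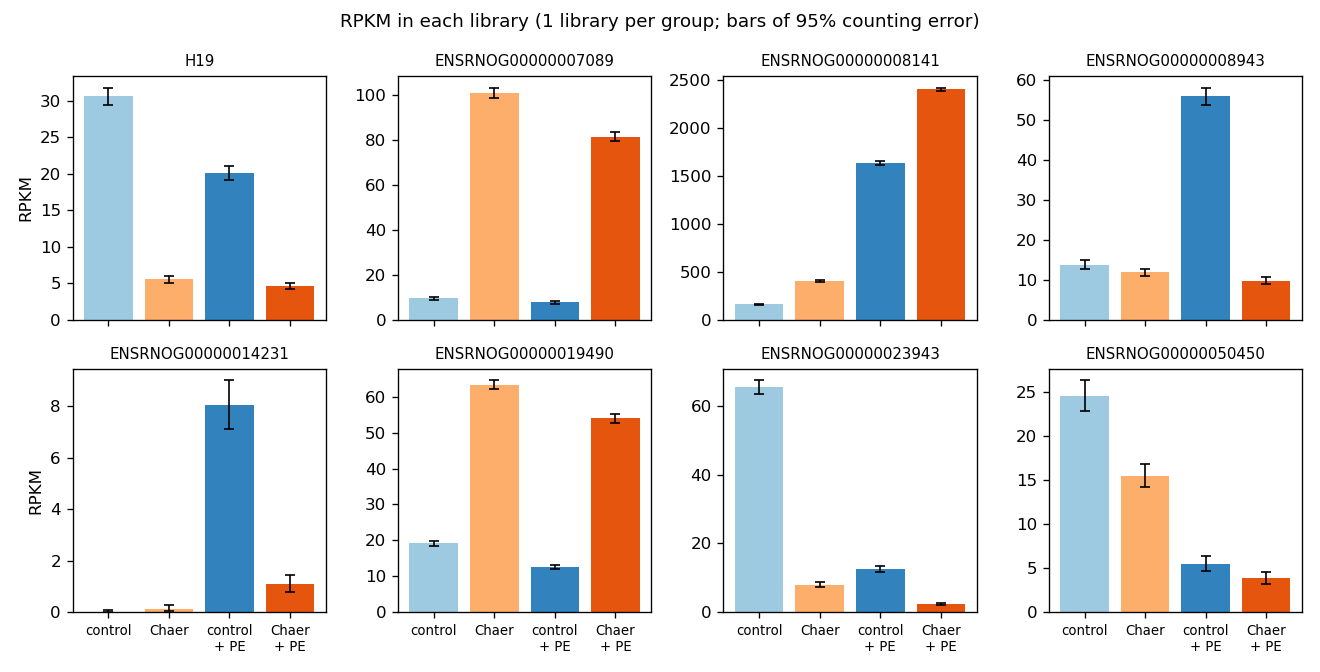
RPKM (y, from 0) of H19 and of 7 features given by identifier in each of the 4 libraries (x; control and Chaer name the siRNA, PE is phenylephrine), with 1 library per group and error bars of exact 95% Poisson counting intervals. H19 was at 30.6 and 20.1 RPKM with control siRNA and at 5.52 and 4.60 RPKM with Chaer siRNA, and ENSRNOG00000008943 was high in the control siRNA library with phenylephrine alone.

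The difference of the phenylephrine effects reached 2-fold for 66 features, 39 higher and 27 lower with Chaer siRNA. Poisson draws with no change, which hold counting error only, gave a median of 11 and at most 17. The SD of the log2 difference was 0.31, against 0.13 in the draws. Variation between cultures is not in the draws, so this gap does not tell an effect of the siRNA from such variation. ENSRNOG00000008943 was 4.05-fold higher (3.72 to 4.42) with phenylephrine under control siRNA and 1.22 times lower (1.08 to 1.38) under Chaer siRNA, a log2 difference of -2.21. ENSRNOG00000014231 had a log2 difference of -2.28, with 0 and 5 reads in the untreated libraries and 288 and 45 reads in the treated ones. That value depended on the pseudocount, at -1.13 with 5 and -3.93 with 0.1. The counting interval for this feature ran from -10.41 to -2.01, but it was taken on log read counts and not on RPKM with a pseudocount. It therefore belongs to another estimate of the difference and is not centred on -2.28. ENSRNOG00000008141 had a log2 difference of -0.74, and H19 of 0.37. Of the features past 2-fold, 59.1% were higher, and 69.9% and 76.8% under median-ratio scaling and without the 20 most abundant genes. With both main effects in the model no residual degree of freedom is left for a test of this difference. An edgeR fit of the difference alone, with both main effects in the error, called 0 features, and 20 had an unadjusted p under 0.05. The main effects held 44.7% and 45.5% of the squared log2 differences, so that error was large. The fit could hardly call any difference, and its result does not count against one.

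Over all 4 libraries, the sum of squared log2 differences divided into 44.7% along phenylephrine, 45.5% along the siRNA and 9.85% along the departure from additivity. The additive edgeR quasi-likelihood fit called 1071 features higher and 806 lower with phenylephrine at an adjusted p under 0.05. With Chaer siRNA it called 1154 higher and 1243 lower. These calls and the SEs below rest on departures from additivity over all genes, since no group had a replicate. Scaling by library size alone in place of TMM gave 694 higher and 1229 lower with phenylephrine, so the split between directions depended on the scaling. For Chaer siRNA the larger direction turned with DESeq2, to 638 higher and 411 lower. It also turned with a mean RPKM of at least 5, to 756 and 616. ENSRNOG00000007089 rose with Chaer siRNA by 3.41 ± 0.16 (SE) on the log2 scale, and ENSRNOG00000008141 rose with phenylephrine by 3.05 ± 0.16 (SE). With the other factor left out of the edgeR model these terms had adjusted p = 0.0161 and adjusted p = 0.119. In those models, 8 features were called for phenylephrine and 1 for Chaer siRNA, and 1217 and 1615 had an unadjusted p under 0.05.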

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

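All tests of explanations given here, of scaling for H19, of regression to the mean and of a difference common to all genes, were set after their results were seen, and the edgeR fit of the difference of the effects was added after seeing the data. The pseudocounts, filters and scalings behind the H19 range and the shares by choice of siRNA had been planned. ENSRNOG00000008943 had phenylephrine log2 ratios of opposite sign, 1.94 under control siRNA and -0.26 under Chaer siRNA, a difference of -2.21. The second shows no rise and lies within the spread of all features in that comparison, whose median was -0.10 and SD 0.38. That spread is not an error for this feature, whose counting interval was 1.08 to 1.38 times lower. Whether it moved the other way is therefore not settled. ENSRNOG00000014231 had Chaer siRNA log2 ratios of opposite sign, 0.17 without and -2.11 with phenylephrine, a difference of -2.28, but the first of these rests on 0 and 5 reads, and the difference was -1.13 with a pseudocount of 5 and -3.93 with 0.1. Each rests on 1 library per group, and the differences were not tested with the main effects in the model. With the main effects in the error, edgeR gave both an adjusted p = 1.00, but that error was too large for the fit to count against a difference.

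H19 was lower with Chaer siRNA in both conditions. The scaling between libraries is argued against as the cause, since the highest of its log2 ratios over the pseudocounts, filters and scalings run was -1.39, reached with a pseudocount of 5. Still open are an effect of lowering Chaer and an effect of this siRNA on other transcripts, since the level of Chaer was not analysed here. A difference between cultures also stays open, since the labels do not say which libraries came from separate cultures. Were the libraries of each siRNA to share a culture, a single difference could give both ratios. Without replicates it was not tested.

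Among features at least 2-fold higher with phenylephrine under control siRNA, 102 of 137 (74.5%) had the smaller ratio under Chaer siRNA. Regression to the mean is a candidate explanation, since choosing the features on the Chaer siRNA ratio gave 41.0% (32.6% to 49.9%), the opposite order. Chosen on the mean ratio, the share of 62.2% became 55.1% (46.0% to 63.9%) after centring on all genes. That interval holds both an even split and the uncentred share, so a smaller response of the raised features with Chaer siRNA may exist or may be a shift common to all genes. The shift also varied with level. Its median went from 0.02 in the fifth of features with the lowest mean RPKM to -0.15 in the fifth with the highest. Centring on a single median does not remove that trend.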

How the results depend on the processing

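No paired analysis was possible because each group holds 1 library and no replicate number pairs them; the additive fit does compare each factor within the levels of the other. No library can be left out, since a group would vanish and the additive fit would have no residual degree of freedom. The gene list medians planned were not run, because the identifiers are not paired with symbols. The additive fit and its alternatives, the 20-read minimum and the centring were chosen after seeing the data. In the order phenylephrine with control siRNA, phenylephrine with Chaer siRNA, Chaer siRNA without and Chaer siRNA with phenylephrine, then the difference of the phenylephrine effects, the 1.5-fold rule gave 433, 522, 604, 547 and 553 features higher and 491, 723, 759, 527 and 198 lower. The 4-fold rule gave 13, 15, 1, 2 and 1 higher and 1, 2, 9, 3 and 2 lower. A pseudocount of 5 gave 74, 70, 55, 53 and 6 higher and 19, 26, 37, 31 and 4 lower. A pseudocount of 0.1 moved 8 of the 10 counts by over 1.5 times: to 193, 187 and 138 higher for the siRNA comparisons and the difference, and to 169, 224, 270, 246 and 67 lower. With a mean RPKM of at least 5, the lower counts became 42 for phenylephrine with control siRNA and 84 for Chaer siRNA without phenylephrine, and the difference 20 higher and 12 lower. The difference reached 68 higher on the TPM scale and 63 without the 20 most abundant genes. These follow in part from the construction (a stricter rule, fewer genes); the cause was not tested otherwise. Without a filter, with a counting interval that excludes 1, or with a mean of at least 20 reads, all 10 counts stayed within 1.5 times. Counting error alone put at most 8 features past 2-fold in each of the 4 comparisons between libraries, but a median of 11 and at most 17 for the difference of the effects, so depth bears on the 66 found there.

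Both Pearson correlations and the slope stayed within 10% under the 7 settings run, with the slope between 1.12 and 1.16; Spearman's rho fell to 0.43 for phenylephrine and 0.47 for Chaer siRNA without a filter. The share of raised features with the smaller phenylephrine ratio under Chaer siRNA was 74.5% when chosen on the control siRNA ratio and reversed to 41.0% when chosen on the Chaer siRNA ratio. For lowered features it reversed to 63.5% and became 9.35%, and it was 50.0% with a pseudocount of 5. The additive fit's counts for phenylephrine were 694 higher and 1229 lower by library size alone, 679 and 466 with a mean RPKM of at least 5, 561 and 341 with DESeq2, and 8 and 0 with the other factor left out of the model (1217 at an unadjusted p under 0.05). For Chaer siRNA they were 756 and 616, 638 and 411, and 1 and 0 (1615 unadjusted) under the last 3 of these settings. The lower H19 ratios with Chaer siRNA and the ratios of 2-fold or more of ENSRNOG00000007089, ENSRNOG00000008141, ENSRNOG00000008943, ENSRNOG00000019490 and ENSRNOG00000050450 kept their direction and their side of 2-fold in each alternative. ENSRNOG00000023943 with phenylephrine and Chaer siRNA was at -0.83 with a pseudocount of 5, where its difference of effects was 1.19. ENSRNOG00000014231 passed 2-fold with phenylephrine under Chaer siRNA at a pseudocount of 0.1 (2.42) and on the TPM scale (1.26), and with Chaer siRNA alone at a pseudocount of 0.1 (1.15).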

Other observations

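The additive edgeR fit, the overlap of its calls, its comparison within bins of mean reads and the scalings and other tools run on it were chosen after seeing the data; the tests of a single high library, few reads and scaling were set before their own values were seen. Features called lower with phenylephrine and also lower with Chaer siRNA numbered 199, against 81.9 for independent lists. Higher with both were 154 features, against 101. Higher with phenylephrine and lower with Chaer siRNA were 138, against 109, and lower with phenylephrine and higher with Chaer siRNA were 96, against 76.1. These contrasts use the same 4 libraries. With DESeq2 in place of edgeR 60 features were lower with both, all among the 199, against 11.5 for independent lists. With the other factor left out of each edgeR model 0 features were called lower with either (1217 had an unadjusted p under 0.05 for phenylephrine and 1615 for Chaer siRNA), so the set rests on the model with both factors. Across all genes the contrasts correlated at r = 0.06, against -0.01 to 0.04 in 20 simulations with no effect of either factor. The covariance was 0.00972, against a simulated median of 0.000104. Contrasts simulated without effects spread less, so the gap in covariance follows in part from the construction. Part of the excess over independent lists can come from the shared libraries.

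For the 199 features lower with both, a single high library, the untreated control siRNA one, is argued against for the set as a whole. Their median Chaer siRNA log2 ratio among the phenylephrine libraries was -0.66 relative to all genes. That ratio is part of the term on which they were chosen, so the choice itself pushes it below 0. Their phenylephrine effects differed between siRNAs by a median of 0.04 relative to all genes. A high untreated control siRNA library would raise that difference, which is not part of either term used for the choice. A median does not cover each feature. Few reads are argued against by a median of 219 reads in the shallowest library, although that is fewer than the 707 of all genes and the 1334.5 of those higher with both; within 10 bins of mean reads, independent lists would share 84.0 features. The scaling is argued against too, since the ratio to independent lists was at least 2.08 under the 3 scalings run, and 188 and 191 of the 199 were called under library size alone and under relative log expression factors. Without a filter 196 features were lower with both, 163 of them among the 199, and with a mean RPKM of at least 5, where 8895 features were tested, 97 were, 96 of them among the 199, against 32.3 for independent lists. A set of transcripts that both treatments lower is a candidate explanation, but a difference in the cells behind the 4 libraries could give the same pattern, and which genes they are stays open.

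From the fifth of features with the lowest mean RPKM to the fifth with the highest, the median log2 ratio went from -0.12 to 0.05 for phenylephrine with control siRNA and from -0.10 to 0.12 for Chaer siRNA without phenylephrine. Both of these ratios use the untreated control siRNA library. Those that do not went from -0.08 to -0.08 for phenylephrine with Chaer siRNA and from -0.06 to -0.03 for Chaer siRNA with phenylephrine. The difference of the phenylephrine effects went from 0.02 to -0.15. From the fifth of features with the shortest gene models to the fifth with the longest, the ratios that use that library went from -0.02 to -0.12 and from 0.05 to -0.05, and the others from -0.12 to -0.04 and from -0.07 to -0.01. Features at least 2-fold above all other libraries numbered 18 in the untreated control siRNA library, 1 in the Chaer siRNA library, 7 with control siRNA and phenylephrine and 4 with Chaer siRNA and phenylephrine. Those at least 2-fold below all others numbered 6, 1, 2 and 13.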
